A study of Mus musculus with 2 samples.

How the data were processed

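RNA was sequenced from 2 cultures of mouse tail keratinocytes, 1 of the genotype Pp6fl/fl and 1 of the genotype K5.Pp6fl/fl. Per the labels' protocols, the cells were grown for 3 days in Medium 154CF, RNA was extracted with Trizol, polyadenylated RNA was captured on oligo(dT) beads, and libraries were made with a TruSeq kit that does not mark the strand of origin. Reads from overlapping genes on opposite strands therefore cannot be told apart. The grouping was taken from the genotype label of each sample. How many mice gave each culture is not stated in the labels.

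The data are 1 table of 47719 genes with an estimated count and an FPKM value per library, and with a log2 fold change, a p-value and an FDR per gene. RSEM, edgeR and the mouse build mm8 are named in the submitters' processing notes without versions or roles. The aligner, the annotation release and the filters are not given in the sources used here. The estimated counts were deposited by the authors after multiplication by 1 constant per library. In the Pp6fl/fl column 97.3% of the values that came to under 100 reads were whole numbers, within 0.01 reads, once divided by 1 step, and in the K5.Pp6fl/fl column 97.4% were. The ratio of the K5.Pp6fl/fl step to the Pp6fl/fl step was 1.118 and their product was 1.0. Dividing each column by its step gave 19374772 estimated reads for Pp6fl/fl and 17361257 for K5.Pp6fl/fl, where the columns as deposited sum to 18323537 and 18357287. All counts below are these estimated reads, rounded to whole numbers for intervals and scaling factors. The scaling of the deposited counts was found only once the table was at hand; the design had assumed unscaled counts. The deposited FPKM values of the authors divide the counts by an effective gene length that can differ between the libraries where isoform shares differ. The log2 fold changes in the authors' deposited table follow the ratio of the FPKM columns: for 10661 genes with over 50 counts in both libraries, their difference from the log2 FPKM ratio had an SD of 0.00886, against 0.153 for the difference from the log2 count ratio. The p-values and FDR of the authors' deposited table rest on 1 library per genotype, and the dispersion used for them is not given in the sources used here.

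Gene symbols were looked up by Ensembl gene ID, and 47219 of the 47719 IDs matched. Genes without a symbol held 0.105% of the Pp6fl/fl counts and 0.106% of the K5.Pp6fl/fl counts. The named build predates these gene identifiers and differs from the reference at hand (GENCODE annotation of GRCm38), so no coordinates are given, and the reference served only for symbols, for which genes overlap, and for GC content and transcript length.

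Depth-scaled read counts in CPM were computed on TMM-scaled library sizes (edgeR 4.0.16 in R 4.3.3). The TMM factors were 0.99869187 for Pp6fl/fl and 1.0013098 for K5.Pp6fl/fl. With 1 library per genotype there was no spread between replicates to test against, so the main comparison has no p-value; an edgeR exact test with an assumed spread between cultures was run only as an alternative. For each gene the fold is the ratio of CPM, K5.Pp6fl/fl over Pp6fl/fl, with an exact conditional binomial (Clopper-Pearson) interval at 95%, and the log2 ratio was taken after adding 0.5 CPM to both values, which pulls the ratios of low genes towards 0. A gene was counted as at least 2-fold higher or lower when the log2 ratio was at least 1 in size, the larger value was at least 1 CPM and the interval excluded a ratio of 1. Genes with at least 1 CPM in a library are called expressed. Intervals of single counts are exact Poisson intervals. All intervals cover counting error only, since reads without molecular identifiers are not independent molecules and cultures of 1 genotype also differ from each other. At 50 CPM or more the log2 interval reached at most 0.16 to either side of its own midpoint, and it was much wider for genes near 1 CPM.

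Before the data were examined, 41 gene lists were fixed for keratinocyte states, signalling, the cell cycle, metabolism, PP6 and its relatives, and markers of other skin cell types, together with a check list of sex-linked genes. For each list the expressed members were counted and the median log2 ratio was placed among 10000 random lists of the same size matched on mean expression in 20 bins. This percentile describes these 2 libraries and is no test. Lists with under 5 expressed members have counts only. The genes named in the text were chosen by a rule also fixed before the data were examined. It takes Ppp6c and the other PP6 subunits; the 12 highest and 12 lowest log2 ratios among genes past the 2-fold rule at 5 CPM or more; in each list up to 4 members past the rule with the largest ratios or, where none passed, the 2 most abundant; and for marker lists the 3 most abundant. Genes from outside the rule are said to be so where they are named, and 2 genes that the rule takes are not reported here. The fold rule, the interval, the list percentile and the removal of a GC and length trend were tested on simulated data in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. For the comparison of 2 libraries over 47719 simulated genes, 0 of 50 genes with a 1.5-fold change passed the 2-fold rule, 49 of 50 passed at 2.5-fold and 50 of 50 at 4-fold, while 2 of 12090 unchanged expressed genes passed. The counting interval held the true ratio for 95.3% of unchanged genes. The simulated libraries differed by counting error only, with no spread between cultures. These rates therefore check the calculation and are no error rates for real cultures.

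Alternatives fixed in advance were library totals, DESeq2 1.42.0 size factors, other pseudocounts, filters and fold thresholds, FPKM in place of counts, totals without the most abundant genes, and, for lists, the mean, other member filters and unmatched random lists. Alternatives added after the data were seen were FPKM for Ppp6c and for the lists, removal of a smooth trend on GC content and transcript length, the count columns as deposited, and an edgeR exact test with assumed coefficients of variation between cultures. No column of values per sample was left unused.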

Results

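Transcripts of cultured mouse keratinocytes, the main cell type of the epidermis, were measured by RNA sequencing in 1 library from Pp6fl/fl cells and 1 library from K5.Pp6fl/fl cells. Pp6 encodes the catalytic subunit of protein phosphatase 6 (PP6), a serine/threonine phosphatase of the PP2A family, and is named Ppp6c in the table. In the K5.Pp6fl/fl mice the floxed allele is deleted by a recombinase under the keratin 5 promoter, which is active in basal keratinocytes, and the Pp6fl/fl cells without it are the control. The cells came from tails of C57BL/6J mice aged 8 weeks and were cultured for 3 days. The Pp6fl/fl library held 19374772 estimated reads in genes and the K5.Pp6fl/fl library 17361257. There were no replicates, so none of the differences below has a replicate check, and every interval (95%) covers counting error only.

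The first comparison concerns the targeted gene itself. Ppp6c (ENSMUSG00000026753) had 1074 reads in the Pp6fl/fl library (exact Poisson interval 1010 to 1140) and 707 in the K5.Pp6fl/fl library (656 to 761). This corresponds to 55.5 and 40.7 CPM, a fold of 0.733 (0.665 to 0.806), which is 26.7% lower and short of the 2-fold rule. By FPKM the difference was larger, from 30.6 to 16.8, a fold of 0.548, and the authors' deposited table lists a log2 fold change of -0.86 with an FDR of 5.71e-06. The lower value was in the library labelled K5.Pp6fl/fl. Reads outside the deleted part of the gene and cells that kept the gene would both count here, since the table has no values per exon. Among the other PP6 subunits, the regulatory subunits Ppp6r1 and Ppp6r3 had folds of 0.993 (0.944 to 1.04) and 1.04 (0.985 to 1.09). The ankyrin repeat subunits Ankrd28, Ankrd44 and Ankrd52 had folds of 0.993, 1.07 and 1.02, each with an interval that included 1. Ppp6r2 had a fold of 0.798, with an interval (0.622 to 1.02) that also included 1. Of 9 catalytic subunits of related phosphatases none was 2-fold apart. Ppp1cb of protein phosphatase 1 was at 350 and 471 CPM, a fold of 1.35 (1.3 to 1.39), and Ppp1ca at a fold of 0.958 (0.924 to 0.994).

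Few genes differed by 2-fold or more between the genotypes, and most of these were higher in the K5.Pp6fl/fl library. Of 12326 expressed genes, 100 were at least 2-fold higher and 24 at least 2-fold lower, together 1.01%. Among the 4538 genes at 50 CPM or more, 6 were higher and 0 lower. They were the alarmin cytokine Il33, the neutrophil-attracting chemokine Cxcl1, the cornified envelope genes Sprr2a1 and Lce3d, the immediate early transcription factor Egr1 and the glutaredoxin Glrx, of which Lce3d (2.02-fold, 1.92 to 2.13) and Glrx (2.29-fold, 2.1 to 2.51) lie outside the naming rule and were chosen after their values were seen. Across expressed genes the log2 values of the libraries had a Pearson r of 0.991, a correlation over genes that are not independent replicates, and the middle 95% of log2 ratios lay between -0.47 and 0.69. The count of 2-fold genes depends on the treatment of low genes. It was 173 higher and 57 lower with a pseudocount of 0.1 CPM and 33 and 5 with 2 CPM. With FPKM in place of counts it was 232 and 140, of which 58 and 8 were also past the rule by counts. The FPKM setting required no counting interval, and its pseudocount of 1 and its floor were in FPKM. Rule and measure therefore changed together.

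**Figure D1:**
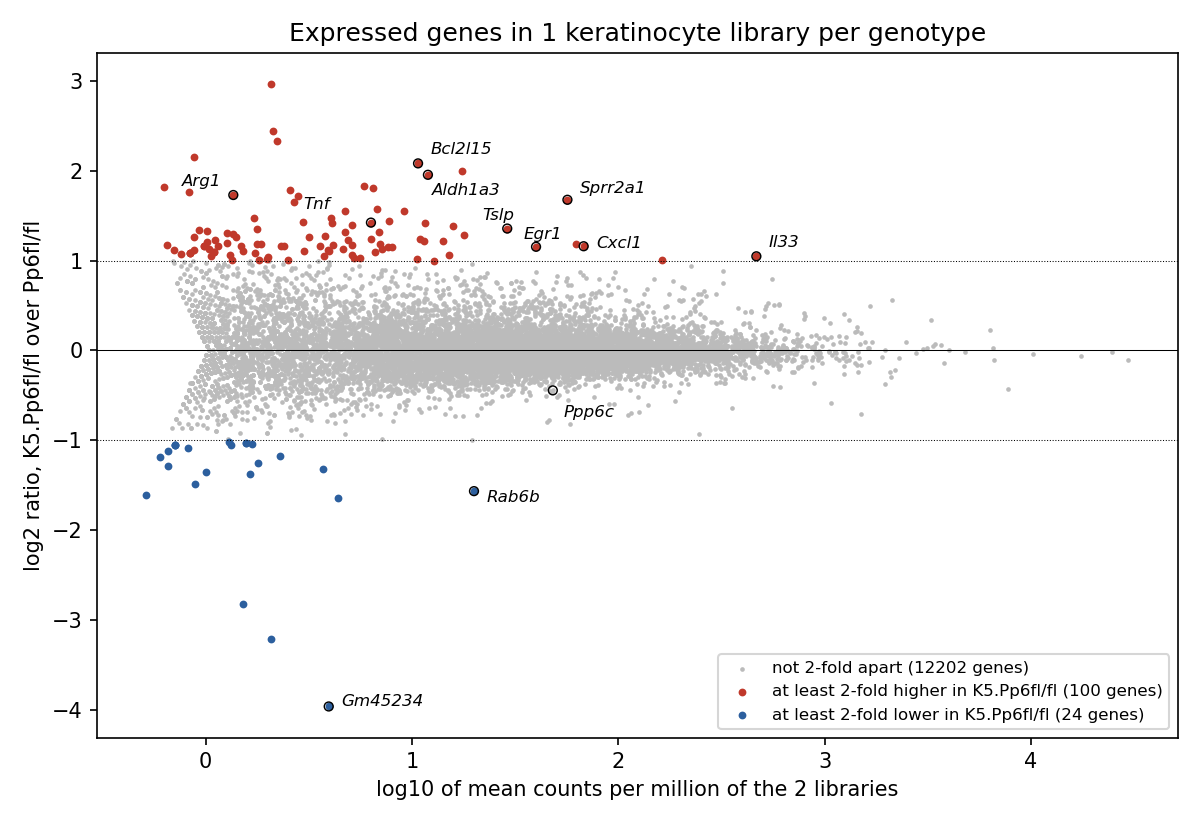
Each point is 1 of 12326 expressed genes, with the log10 of its mean CPM over both libraries on the x axis and its log2 ratio, K5.Pp6fl/fl over Pp6fl/fl, on the y axis; dotted lines mark 2-fold. The 100 red points outnumber the 24 blue ones, most lie at low abundance, and Ppp6c lies at -0.44.

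Among genes at 5 CPM or more, 49 were at least 2-fold higher and 4 at least 2-fold lower. The highest ratio was that of Bcl2l15, a gene of the Bcl2 family, with 73 and 306 reads, a fold of 4.66 (3.6 to 6.11). Aldh1a3, which makes retinoic acid from retinal, was 4.19-fold higher (3.31 to 5.35), and Tnfrsf11b, which encodes the RANKL decoy receptor osteoprotegerin, 4.12-fold (2.94 to 5.89). Cyp1b1, a cytochrome P450 of the aryl hydrocarbon receptor response, was 3.16-fold higher (2.45 to 4.09). The RNA-binding protein gene Rbms3 was 3.3-fold higher (2.46 to 4.49), and Fras1, an extracellular matrix protein of the basement membrane, 3.37-fold (2.36 to 4.89). By FPKM Fras1 was 12.1-fold higher, from 0.139 to 1.69, so its size depends on the measure. Several of the highest genes have near-identical copies that share reads, so their own ratios are uncertain. Prl2c3 stood at 3.98-fold, and the sum of Prl2c2, Prl2c3 and Prl2c5 at 4.69-fold (3.57 to 6.23). Gm6166, a processed pseudogene, stood at 4.2-fold, but its sum with the fatty acid binding protein gene Fabp5 was 1.47-fold higher (1.39 to 1.56). Scgb2b27 stood at 2.94-fold (2.25 to 3.89), and the sum of 33 Scgb2b genes at 2.91-fold (2.22 to 3.83).

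Only 4 genes at 5 CPM or more were at least 2-fold lower, and 3 of them are gene models that overlap other genes. Rab6b, a small GTPase of Golgi transport, had 582 and 171 reads, a fold of 0.327 (0.274 to 0.388). Gm45234 had 152 reads against 1 (0.00464-fold, 0.000184 to 0.0414) and overlaps Atn1 on the same strand. The sum of both genes did not differ, with a fold of 1.0 (0.945 to 1.06). Gm42890 (0.271-fold, 0.183 to 0.407) overlaps Wdr77, Ovgp1 and Atp5f1. Gm44460 (0.346-fold, 0.227 to 0.516) is a short microRNA model opposite to the keratin gene Krt75, which strand-blind reads cannot be separated from, and it did not pass with a pseudocount of 2 CPM. From 106 reads it took the highest FPKM of the Pp6fl/fl library, 40047, which was 4.94% of that library's summed FPKM.

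Genes of terminal differentiation, which builds the outer layers of the epidermis, were higher as a group in the K5.Pp6fl/fl library. Of 39 expressed members of the granular layer and cornified envelope list, 38 had a log2 ratio above 0 and 31 an interval above 1. The median log2 ratio was 0.60, at the 100th percentile of matched random lists, and 4 members were at least 2-fold higher. These were Sprr2a1 (3.24-fold, 2.93 to 3.59), Sprr2e (3.25-fold, 2.22 to 4.86), loricrin, Lor (2.35-fold, 1.82 to 3.07), and Flg2, a filaggrin relative (3.9-fold, 1.89 to 8.82, from 10 and 35 reads). Because the Sprr2a genes share reads, the sum of Sprr2a1, Sprr2a2 and Sprr2a3 is the safer value, at 2.18-fold (2.03 to 2.34). The sum of all 13 Sprr2 genes, Sprr2e among them, was lower, at 1.71-fold (1.63 to 1.78). Lor and Flg2 no longer passed with a pseudocount of 2 CPM. The most abundant members differed less. The envelope protein gene Sprr1a was at 1160 and 1460 CPM, a fold of 1.26 (1.24 to 1.28). Corneodesmosin, Cdsn, was 1.52-fold higher (1.46 to 1.59), and the kallikrein protease Klk7 1.58-fold (1.52 to 1.65). Of 13 expressed suprabasal genes none was 2-fold apart, and the median was 0.31, again at the 100th percentile. Sbsn and Dmkn were 1.33-fold (1.3 to 1.37) and 1.24-fold (1.22 to 1.27) higher, while the transcription factor Klf4 was at 0.94 (0.907 to 0.974). The list was mixed, with 4 members below 0. One of them was the spinous keratin Krt10, at 0.77-fold (0.658 to 0.898), named here after its value was seen. Genes of epidermal barrier lipids had a median of 0.19, at the 100th percentile, with the lipid transporter Abca12 1.35-fold higher (1.3 to 1.41) and the ceramide desaturase Degs1 at 0.916 (0.868 to 0.967).

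Basal keratinocyte genes were close to equal in the libraries as a group, though single members went both ways. The 15 members had a median log2 ratio of -0.08, at percentile 2.54, and none was 2-fold apart. Their log2 ratios ran from -0.37 to 0.54, with 9 intervals below 1 and 5 above. The basal keratins Krt14 and Krt5, among the most abundant transcripts of both libraries, had folds of 0.93 (0.927 to 0.934) and 0.961 (0.956 to 0.965). The stress keratins Krt6a and Krt17, of wounded or cultured epidermis, were at 0.989 (0.985 to 0.993) and 0.971 (0.965 to 0.977), and Krt16 was 1.27-fold higher (1.25 to 1.28). The list of 5 stress keratins had a median of -0.02, at percentile 47.42. Its members ran from -0.58 to 0.76 in log2 ratio, with 2 intervals above 1 and 3 below.

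Cytokine genes of the keratinocyte were among the larger differences. Of 12 expressed IL-1 family genes, 10 had a ratio above 0 and 4 were at least 2-fold higher, with a median log2 ratio of 0.73 (100th percentile). Il33 was the most abundant of them, with 5880 and 10929 reads, or 304 and 629 CPM, a fold of 2.07 (2.0 to 2.14). The IL-33 receptor gene Il1rl1 (3.44-fold, 1.7 to 7.53; 2.21-fold by FPKM), Il18 (3.76-fold, 1.66 to 9.57) and Il1f6, which encodes IL-36 alpha (3.66-fold, 1.52 to 10.1), rested on 7 to 11 reads in the Pp6fl/fl library, and none of the 3 passed with a pseudocount of 2 CPM. Among 15 other expressed cytokines and growth factors, 13 had a ratio above 0, with a median of 0.32 (100th percentile). Past the 2-fold rule were Tslp, an alarmin of allergic inflammation, at 2.61-fold (2.28 to 2.99), Tnf at 2.94-fold (2.19 to 4.01) and the macrophage growth factor Csf1 at 2.1-fold (1.69 to 2.61), the last not with a pseudocount of 2 CPM.

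Of 10 expressed chemokine genes, 8 had a ratio above 0 and 2 below, and 3 were at least 2-fold higher, with a median of 0.22 at percentile 98.54. This placement was not kept at a floor of 5 CPM (percentile 94.34), over all measured members (96.26) or by FPKM (94.76). Cxcl1 was 2.25-fold higher (2.07 to 2.45). The monocyte chemokine Ccl2 (3.74-fold, 1.87 to 8.14) and Ccl20, which attracts cells with CCR6 (2.89-fold, 1.56 to 5.65), were near the floor, with 11 and 15 reads in the Pp6fl/fl library. These 2, S100a8 and Tnfaip2 did not pass with a pseudocount of 2 CPM. In the list of S100 and antimicrobial genes, 5 of 18 measured members were expressed, and S100a8 and S100a9, the subunits of calprotectin, were 2.35-fold (1.82 to 3.04) and 2.42-fold (1.96 to 3.01) higher. Their levels stayed low, at 11.2 and 16.2 CPM in the K5.Pp6fl/fl library. In the NF-kB list 1 of 21 expressed genes, Tnfaip2, passed the rule (2.3-fold, 1.59 to 3.38), and the median of 0.07 lay at percentile 97.71. The interferon-stimulated genes had 8 of 28 members expressed, none 2-fold apart, and a median of 0.36 at percentile 99.40. Stat2 was at 0.96 (0.81 to 1.14). Both of these list placements were lost under some settings given with the other alternatives. Among 25 immediate early and MAPK feedback genes the median was 0.02 (percentile 79.21), with 1 past the rule, Egr1, at 2.25-fold (2.01 to 2.52).

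**Figure D2:**
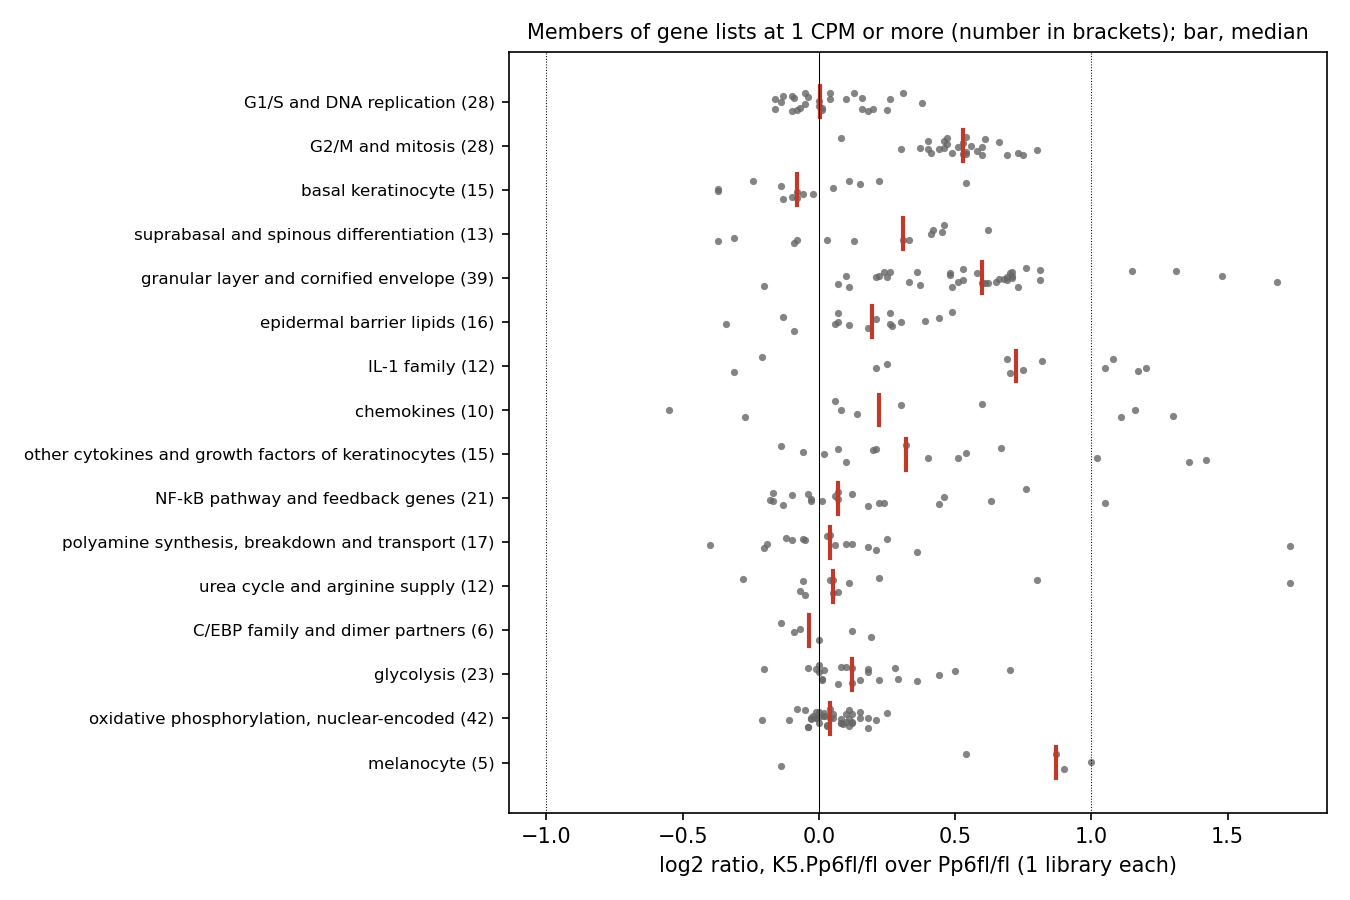
Points are the log2 ratios (x axis, K5.Pp6fl/fl over Pp6fl/fl) of the expressed members of 16 of the fixed gene lists, and red bars are list medians. All 28 points of the G2/M list lie above 0, while the 28 of the G1/S list centre on 0.01.

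Genes of mitosis were higher by under 2-fold in the K5.Pp6fl/fl library, and genes of DNA replication were not. All 28 G2/M genes were expressed and had log2 ratios above 0, from 0.08 to 0.80, and for 27 the interval lay above 1. The median was 0.53 (1.44-fold), at the 100th percentile, and none reached 2-fold. The proliferation marker Mki67 was at 433 and 597 CPM, a fold of 1.38 (1.34 to 1.42), and the topoisomerase gene Top2a was 1.39-fold higher (1.33 to 1.45). The 28 G1/S genes had a median of 0.01 (percentile 76.46), with ribonucleotide reductase Rrm1 at 1.08 (1.04 to 1.11) and the helicase subunit Mcm6 at 0.932 (0.896 to 0.969). CDK inhibitor and senescence genes had a median of 0.27 (percentile 99.97), with 10 of 10 expressed members above 0 and none 2-fold apart. The list joins genes that rise in senescent cells with Lmnb1, which falls in them, so its median is no measure of senescence. In the authors' deposited table Lmnb1 had a log2 fold change of 0.21. Cdkn1a, the p21 gene, was 1.14-fold higher (1.1 to 1.18) and Igfbp3 1.55-fold (1.46 to 1.64). The p53 target list was at 0.04 (percentile 92.40), with the desmosome gene Perp at 1.04 (1.03 to 1.05). The DNA damage list was at 0.00 (percentile 74.07), with Rpa1 at 0.968 (0.921 to 1.02) and Mdc1 at 0.916 (0.865 to 0.97).

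Arginine and polyamine metabolism was examined because arginase 1 supplies ornithine for polyamine synthesis. Arg1 had 7 reads in the Pp6fl/fl library and 41 in the K5.Pp6fl/fl library, 0.362 and 2.36 CPM, a fold of 6.52 with a wide interval (2.9 to 17.2). It was the only member past the 2-fold rule among 17 expressed polyamine genes, whose median log2 ratio was 0.04 (percentile 87.16), and among 12 expressed urea cycle and arginine genes, whose median was 0.05 (percentile 89.39). With a pseudocount of 2 CPM its log2 ratio of 1.73 became 0.88 and no longer passed. The rate-limiting polyamine enzyme Odc1 was at 1.08 (1.04 to 1.12) and the acetyltransferase Sat1, which starts polyamine breakdown, at 0.759 (0.717 to 0.804), both named after their values were seen. The 6 expressed C/EBP genes and partners had a median of -0.04 (percentile 37.38), with Atf4 at 0.998 (0.973 to 1.02) and Cebpg at 0.953 (0.899 to 1.01).

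The medians of the energy metabolism lists were small. The 23 expressed glycolysis genes had a median of 0.12 (percentile 99.95), with pyruvate kinase Pkm at 1.07 (1.05 to 1.08) and enolase Eno1 at 1.05 (1.03 to 1.07). Single glycolysis genes ran from -0.2 to 0.7 in log2 ratio, 18 above 0 and 5 below, with 12 intervals above 1 and 1 below. The 42 nuclear-encoded genes of oxidative phosphorylation had a median of 0.04 (percentile 99.18), a placement lost by the mean (95.5), unmatched lists (95.26), FPKM (92.03) and the GC and length correction (93.22). The ATP synthase subunits Atp5b and Atp5a1 were at 1.07 (1.05 to 1.09) and 1.03 (1.01 to 1.05). The TCA cycle list was at -0.02 (percentile 40.16), with Mdh2 at 0.957 (0.924 to 0.991) and citrate synthase, Cs, at 1.02 (0.983 to 1.06). Fatty acid and cholesterol synthesis was at -0.03 (percentile 21.27), with Scd2 at 1.15 (1.13 to 1.17) and Hmgcs1 at 1.02 (0.999 to 1.04). None of the members of these lists was 2-fold apart.

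Among stress and matrix lists no member was 2-fold apart either. The 21 expressed NRF2 and oxidative stress genes had a median of 0.17 (100th percentile), although their most abundant members, Prdx1 and Gpx1, were at 0.972 (0.946 to 0.999) and 1.07 (1.03 to 1.11). The 22 TGF-beta and matrix genes had a median of 0.25 (100th percentile), with Itgav at 1.07 (1.02 to 1.12) and Mmp14 at 0.973 (0.927 to 1.02). The 12 YAP and TEAD targets were at -0.08 (percentile 2.24), a placement lost under 5 alternatives, among them the mean (percentile 10.38) and the GC and length correction (13.68). In this list Amotl1 was at 0.888 (0.864 to 0.911) and Ajuba at 0.946 (0.918 to 0.975). The unfolded protein list was at 0.02 (percentile 83.77), with the chaperone Hspa5 at 1.1 (1.07 to 1.13), and the heat shock list at 0.03 (percentile 86.06), with Hsp90ab1 at 1.02 (1.01 to 1.04). The small heat shock protein gene Hspb1 was lower, at 0.743-fold (0.737 to 0.748). The list of EMT factors and cadherins was at 0.06 (percentile 87.20), with E-cadherin, Cdh1, at 1.09 (1.06 to 1.11) and the splicing factor Esrp1 at 1.0 (0.958 to 1.05). This list joins epithelial and mesenchymal genes, so its median gives no direction. Its 8 expressed members ran from -0.37 to 0.88 in log2 ratio, 5 above 0 and 3 below.

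Markers of melanocytes, fibroblasts, T cells, endothelial, Merkel and muscle cells were low in both libraries, while genes of the hair follicle and sebaceous lists, some of which keratinocytes also express, summed to 706 and 512 CPM in the Pp6fl/fl library. Melanocyte genes were higher in the K5.Pp6fl/fl library, with a median of 0.87 over 5 expressed members (percentile 99.98) and 0.47 over all measured members (99.92). The pigment cell genes Pmel and Tyrp1 were at 2.23-fold (1.52 to 3.31) and 1.99-fold (1.39 to 2.9), and the melanocyte transcription factor Mitf at 0.9 (0.694 to 1.17). With 0.5 CPM added, neither Pmel nor Tyrp1 passed the 2-fold rule. Pmel, at 2.17 and 4.83 CPM, overlaps Dgka (172 and 171 CPM) and Cdk2 (43.5 and 43.4 CPM) on the opposite strand. Strand-blind reads cannot separate these genes where they overlap. The summed level of the list was 14.8 and 22.4 CPM. Of the fibroblast list 4 of 16 genes were expressed, with Sparc at 20.8 and 19.4 CPM and Fbln1 at 7.91 and 9.84 CPM. Among T cell genes only Thy1, which fibroblasts also express, reached the floor, at 2.69 and 1.78 CPM, and Lck and Trdc had at most 4 reads. Of 16 measured genes of the Langerhans cell and macrophage list 3 were expressed, with 1 above 0 and 2 below. Epcam was at 67.5 and 124 CPM (1.84-fold, 1.72 to 1.98), Cd68 at 0.84 (0.74 to 0.953) and Cd14 at 0.731 (0.529 to 1.0). Epcam also stands in the list of EMT factors and cadherins and is not specific to Langerhans cells. The endothelial gene Flt1 was at 7.18 and 6.85 CPM, and Eng and Pecam1 were under 1 CPM. The Merkel cell keratins Krt18 and Krt8 were at 1.23 (0.948 to 1.59) and 1.51 (1.08 to 2.11), and the synaptic gene Syp had 2 reads and 0. Smooth muscle genes were at 0.85 (0.714 to 1.01) for Acta2 and 1.57 (1.04 to 2.41) for Tagln, and the skeletal muscle gene Mylpf had 6 and 19 reads. Tagln overlaps Pcsk7 (35.7 and 33.1 CPM) on the opposite strand, with the same limit as for Pmel. The hair follicle list had a median of 0.01 (percentile 57.64), with Sox9 at 0.948 (0.92 to 0.978) and Lgr4 at 1.13 (1.02 to 1.26). The list also holds Tcf3, an E protein gene that is not specific to the hair follicle, at 0.94 (0.876 to 1.01). Sebaceous and sweat gland genes had a median of 0.13 (percentile 88.64), with Plin2 at 1.08 (1.03 to 1.12), Scd1 at 1.1 (1.05 to 1.15) and Krt7 at 1.08 (1.0 to 1.17). Both libraries held the X-inactivation transcript Xist, at 288 and 255 CPM, and Y-linked transcripts, with Ddx3y at 36.3 and 51.8 CPM. Xist marks female cells and Y-linked transcripts male cells. Each culture therefore appears to have held cells of both sexes, and so of more than a single mouse.

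**Figure D3:**
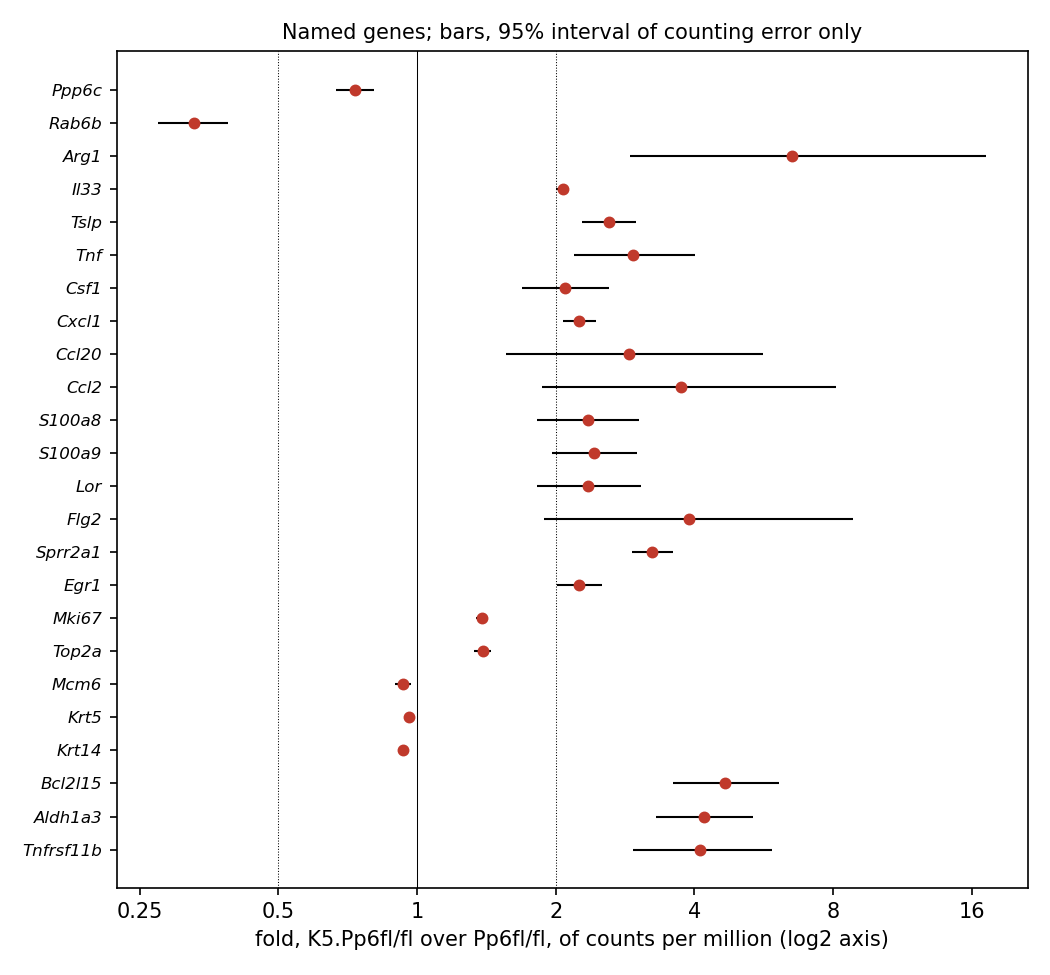
Points are folds of CPM, K5.Pp6fl/fl over Pp6fl/fl, on a log2 axis for 24 named genes, and bars are 95% intervals of counting error only; dotted lines mark 2-fold. Arg1 (6.52) has the widest bar and rests on 7 and 41 reads, and Il33 (2.07) has a narrow one.

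In all, 35 lists were given a percentile. Of these, 16 lay in the highest 2.5% of matched random lists and 1, the YAP and TEAD targets, in the lowest 2.5%. For lists of independently drawn genes 1.75 would be expected beyond either limit, and in the simulation 3 of 40 unchanged random lists were. Members of a fixed list can vary together between any 2 cultures, and some lists share genes, such as Arg1 and Cdkn1a. The excess over 1.75 is therefore no test. The other 6 lists had too few expressed members.

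The authors' deposited table lists 1094 genes with an FDR under 0.05 and a higher level in K5.Pp6fl/fl cells, and 680 with a lower one. It marks 136 higher and 34 lower genes as significant, and all 170 have an FDR under 0.05 and a log2 fold change of 1 or more in size. Of these 170, 113 were also at least 2-fold apart by counts in the same direction (92 higher, 21 lower), and 53 had a count log2 ratio under 1 in size. In counts that can overlap with the 53, 3 had the opposite sign and 4 were under 1 CPM in both libraries. In the authors' deposited table the lowest FDR values include those of Il33 (3.05e-87, log2 fold change 1.06) and Sprr2a1 (5.37e-87, 1.69). For the G2/M list the authors' deposited table has 27 of 28 genes past an FDR of 0.05, each higher, and for the cornified envelope list 29. For Arg1 it gives a log2 fold change of 2.37 with an FDR of 8.08e-06. These values compare 2 libraries, not the conditions. With an assumed coefficient of variation between cultures of 0.2, an edgeR exact test on the estimated reads put 9 genes higher and 3 lower at an FDR of 0.05, and with 0.4 it put 0 higher and 3 lower.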

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

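With 1 library per genotype, no replicate could be left out and no spread between cultures was available. No paired analysis was possible because each genotype has 1 library. Tests with FPKM for Ppp6c and the lists, a GC and length correction, the deposited count values and assumed coefficients of variation were chosen after the data were seen. The table is per gene, so the alternative of counting each row as its own feature did not apply and was not run. The deposited count values were scaled by their own column sums, so their step cancels and that setting nearly repeats library totals. Both settings gave 104 genes higher and 24 lower. The 100 genes at least 2-fold higher and 24 lower stayed within 1.5 times those counts under library totals, median-of-ratios size factors, totals without mitochondrial, ribosomal-protein and the 20 most abundant genes, no filter, the deposited count values and the GC and length correction. They became 173 and 57 with a pseudocount of 0.1 CPM, 33 and 5 with 2 CPM, 49 and 4 at 5 CPM or more, 36 and 7 with the interval wholly beyond 2-fold, 428 and 155 at 1.5-fold, 5 and 3 at 4-fold, and 232 and 140 by FPKM. Fewer or more genes follow from the stricter or looser thresholds themselves. The FPKM setting, which shared 58 and 8 genes with the count rule, also dropped the counting interval and put the pseudocount and floor on the FPKM scale. How much of its difference comes from this and how much from the measure was not tested. The log2 ratio of Ppp6c, -0.44, became -0.83 by FPKM.

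Of 347 list values under an alternative, 325 stayed on their side of the percentile limits, 19 no longer passed, 3 newly passed and 0 reversed; the cause was not tested. The NF-kB median of 0.07 lost its place with a pseudocount of 2 CPM (0.06), unmatched random lists (0.07, percentile 95.22), FPKM (0.06) and the GC and length correction (0.02). The chemokine median lost it at 5 CPM or more (0.14), over all measured members (0.14) and by FPKM (0.12). Interferon-stimulated genes lost it over all measured members (0.16), by the mean (0.3, percentile 96.77) and by FPKM (0.3). Oxidative phosphorylation lost it by the mean (0.05), unmatched lists (0.04), FPKM (0.03) and the correction (0.0). YAP and TEAD targets lost it over all measured members (-0.08, percentile 2.88), by the mean (-0.05), unmatched lists (-0.08), FPKM (-0.08) and the correction (-0.06). Newly past a limit were the basal list with a pseudocount of 2 CPM (-0.08, percentile 2.47), and by the mean the urea cycle (0.22) and immediate early (0.13) lists. The other 12 lists beyond a limit passed under every alternative run for them. Some of their medians moved by over 1.5 times: over all measured members those of melanocyte (0.87 to 0.47), S100 and antimicrobial (0.63 to 0.38) and other cytokine genes (0.32 to 0.21), by the mean that of suprabasal genes (0.31 to 0.18), and by FPKM that of TGF-beta targets (0.25 to 0.15). Of 452 values of named genes, 437 stayed on their side of the 2-fold rule, 12 no longer passed, 3 newly passed and 0 reversed. All 12 were lost with a pseudocount of 2 CPM, which pulls low genes toward equality: Arg1 (0.88), Csf1 (0.89), S100a8 (0.96), Lor (0.96), Gm44460 (-0.94), Tnfaip2 (0.76), Ccl2 (0.68), Flg2 (0.67), Il1rl1 (0.62), Ccl20 (0.61), Il18 (0.56) and Il1f6 (0.49). Newly passing were Pmel with library totals (1.0) and with 0.1 CPM (1.12), and Mylpf with 0.1 CPM (1.54).

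In the authors' deposited table, 1094 higher and 680 lower genes became 136 and 34 with at least 2-fold, and the lower ones 366 at an FDR of 0.01. An edgeR exact test gave 92 and 16 with an assumed coefficient of variation of 0.1, 9 and 3 with 0.2, and 0 and 3 with 0.4. Depth limits genes near 1 CPM most, where about 20 reads leave an interval of several fold.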

Other observations

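The family scan, the GC and length correction, the search for a matching coefficient of variation, the cell cycle test with the G1/S list, the comparisons for swapped labels and remaining transcripts, and the statements on single cultures were chosen only after the results were seen. Families of genes with a shared symbol stem overlap the fixed lists in part. Of the 39 expressed cornified envelope members only 14 lie outside Lce and Sprr, so those 2 families largely restate that list. Of 191 families with 8 or more expressed genes, 9 had a median log2 ratio in the highest 0.5% of matched random lists and 4 in the lowest 0.5%. For groups of independently drawn genes 1.91 would be expected beyond either limit. Members of a family can share reads and vary together, so the excess over 1.91 is no test. All 20 Lce genes and all 13 Sprr genes, both of the cornified envelope, were above 0, with medians of 0.61 and 0.53, and the kallikrein proteases (Klk) stood at 0.53 with 6 of 8 above 0. The Serpinb protease inhibitors had a median of 0.38, with 9 of 11 above 0 and 2 at least 2-fold higher, semaphorins 0.30 with 10 of 11 above 0, and collagens 0.23 with 12 of 15. The keratins (Krt) stood at 0.28 but were mixed, with 14 above 0, 10 below, 2 at least 2-fold higher and 1 at least 2-fold lower. The Atp and Pla stems, which join genes of different function, also lay above the limit, at 0.09 and 0.33. Below the limit were the zinc finger genes, with 207 of 331 Zfp genes below 0 (median -0.06) and 9 of 9 Zscan genes (median -0.26), the Ddx helicases (-0.09) and the Rrp genes of ribosomal RNA processing (-0.16, 7 of 8 below 0).

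Single genes outside the naming rule and chosen after their values were seen are given as values. The amino acid transporter Slc6a14 had 165 and 400 reads, a log2 ratio of 1.38. The serpin Serpinb7 had a log2 ratio of 1.23, the hyaluronan synthase Has2 1.01 from 14 and 34 reads, and the cytokine Il34, a ligand of the CSF1 receptor, 1.11 from 45 and 97 reads. The mucosal keratin Krt13 was lower, at -1.18 from 65 and 21 reads. The Y-linked genes had log2 ratios of 0.51 for Ddx3y, 0.39 for Uty, 0.28 for Eif2s3y and 0.08 for Kdm5d. The interval of Kdm5d included a ratio of 1 (0.935 to 1.2), and Xist was at -0.18. Whether the share of male and female cells differed between the cultures was not tested. In the authors' deposited table, p-values were matched most closely by an edgeR exact test at a coefficient of variation of 0.026 between cultures, among the values tried.

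The first pattern is the G2/M list, with all 28 members above 0. Removing a smooth trend on GC content and transcript length left its median at 0.48, from 0.53, still at the 100th percentile, which argues against such a trend as the whole cause. A larger share of cells in all phases of the cycle would raise the G1/S list too, yet its median was 0.01. A bootstrap over its genes gave an interval of -0.06 to 0.12, wholly below 0.26, which is 0.5 of the G2/M median. That interval leaves out the spread between cultures, so it describes these 2 libraries only. What stays open is variation between single cultures, such as density at harvest, which cannot be told apart from the genotype with 1 library per genotype. The genotype itself also stays open.

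The second pattern is the cornified envelope list, with 38 of 39 members above 0. After removal of the GC and length trend its median was 0.52, from 0.60. Reads moved between near-identical copies would leave genes outside the copied families near 0, but the 14 expressed members outside Lce and Sprr had a median of 0.55 with 13 above 0, and the summed Lce genes were 1.69-fold higher (1.65 to 1.74) and the summed Sprr genes 1.3-fold (1.28 to 1.32). Variation between cultures in how far cells had differentiated stays open, since there was 1 library per genotype. Melanocyte markers were also higher in the K5.Pp6fl/fl library, with a median of 0.87.

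The third pattern is the difference of under 2-fold in Ppp6c. Exchanged labels would put it higher in the K5.Pp6fl/fl library, where its log2 ratio was -0.44 (-0.59 to -0.31), but this interval leaves out the spread between cultures, so with 1 library per genotype an exchange stays open. In FPKM it fell further than in counts, which implies an effective length 1.34 times as long in the K5.Pp6fl/fl library, and only 1.54% of 4420 genes of like count had a ratio as far from 1, so this is not a shift seen in many genes. The table has no values per exon. The level left was 73.3% of that in Pp6fl/fl cells; transcripts of the deleted allele and cells that kept the gene cannot be told apart here as its source.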
